A study of Arabidopsis thaliana with 43 samples.

How the data were processed

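Polyadenylated RNA from leaves of Arabidopsis thaliana seedlings of the Col-0 accession was sequenced in 43 libraries, which covered 11 time points in each of 2 batches. Per the labels' protocols, plates of about 80 seedlings grew at 22 °C with 16 h of light per day. At each time point all leaf tissue of 1 plate was divided between 2 tubes, RNA was extracted with a column kit, and 2 μg per sample entered a stranded mRNA library kit. The plate was therefore the biological replicate, with n = 2 plates per time point, 1 in each batch, and tubes of one plate were technical repeats. One tube of T3 in batch 1 was not analysed here. The protocol text gives the roles of T7, T8 and T9 in the acclimated plants in a way that uses T9 for different kinds of plants. The roles used here follow the sampling temperature and time point labels, which make T7 and T8 acclimated samples and T9 the non-acclimated sample before the shock.

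The deposited counts are whole numbers of reads per locus in a separate table for each library, made by the authors with bcl2fastq 1.8.4, TopHat2 2.0.14, Bowtie2 2.1.0.0, SAMtools and HTSeq on the TAIR10 build, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of overlapping antisense loci may have been counted for either locus. Each count table holds 33602 loci and 5 summary lines, which name no gene and were kept out of library sizes and tests. Their share of all records was 11.7% to 36.2% in batch 1 (median 19.6%) and 14.8% to 45.3% in batch 2 (median 22.5%). The batches differed in its makeup. Records not aligned were 5.69% to 15.2% in batch 1 and 0.174% to 0.303% in batch 2. Those aligned to more than 1 place (multi-aligned) were 3.75% to 24.2% and 13.3% to 44.2%. A second deposited table gives the authors' normalized log2 values for 18864 loci. Its columns have nearly identical distributions, how it was normalized is not given in the sources used here, and it served only as an alternative. Of its per-sample columns 1 matched none of the samples and was not used.

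Counts of the tubes of one plate were summed, and log2 changes were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test used TMM scaling, a filter on low counts (filterByExpr with a smallest count of 10), 1 model over all 22 plates with a term per time point and a batch term, and Benjamini-Hochberg adjustment. In all 20980 loci were tested, with 10 residual degrees of freedom and a common biological coefficient of variation of 0.308. Every adjusted p without another name comes from this test, or for lists from fry in limma 3.58.1, adjusted over the lists of one comparison. Fry's directional p asks whether the members of a list moved, on balance, one way, and its mixed p whether they changed in either direction. Lists pass on the directional p unless the mixed p, given only for some, is named, and neither compares a list with other genes. A gene or list passed, and is said to have risen or fallen, with an adjusted p under 0.05. The error of a log2 change is the standard error of the fit, and levels are given in TMM-CPM as the mean ± SD of 2 plates. Where a time point had 0 counts over both plates, a bound against a floor of 3 counts there replaces the fitted log2 change. With 1 to 3 counts the ratio is given with a 95% counting interval that omits the spread between plates.

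The 14 comparisons, the tests, the alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists were small heat shock proteins; HSP70, HSP90, HSP100 and co-chaperones; heat stress transcription factors; heat memory genes; the unfolded protein response of the endoplasmic reticulum; reactive oxygen enzymes and signalling; abscisic acid and dehydration response; photosynthesis; senescence and chlorophyll breakdown; autophagy; the circadian clock; the cell cycle; salicylic acid and pattern-triggered defence; jasmonic acid response; anthocyanin and flavonoid synthesis; thermomorphogenesis and auxin response; markers of the root, the shoot apex, vascular tissue, and guard cells and the stomatal lineage; and cytosolic ribosomal proteins. The last was drawn from product names and also takes in some organelle ribosomal proteins. The marker lists stand for other tissues that a leaf harvest might hold. In each comparison, named genes are those that rose and those that fell most (6 each in main comparisons, 3 each in others, 5 each in interactions) among genes that passed, with a mean of at least 10 TMM-CPM in 1 of the time points, the same sign in both batches and a gene symbol. HSP101, HSFA2, HSP21, HSP18.2, APX2 and MBF1C, and up to 4 members of each list with the smallest p, could be named in any comparison. Gene names and coordinates came from the RefSeq annotation of TAIR10.1, in which 32835 loci were found by locus ID. Values of near-identical copies are uncertain, because reads may be split between them: HSP90.2, HSP90.3 and HSP90.4, the cytosolic HSC70 genes, BIP1 and BIP2, LHCB2.1 and LHCB2.2, the RBCS genes and the class I small heat shock proteins.

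The test was tried on simulated counts with known changes. For T10 against T9 it recovered 17.6% of 2-fold, 78.8% of 4-fold and 100.0% of 8-fold changes, with 5 unchanged loci called among 20453. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library size scaling alone, no filter on low counts, no batch term, tubes as replicates, a block for the tube number, the plate as a random effect, each batch alone with tubes as replicates, only the plates compared, an added requirement of a 2-fold change, T9 as the reference of T4, and leaving out each plate in turn. When a plate was left out, its time point kept 1 plate, which was assumed to vary like the others. The authors' log2 values, the data without 1 T6 library and the data without organelle genes were alternatives chosen after seeing the data, as were 5 further comparisons, which are named where they are used.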

Results

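Leaf transcripts were followed through a regime that combined heat acclimation, in which the temperature rises slowly, with a later heat shock, in which plants are moved directly to 45 °C. T1 was taken at dawn of day 12 at 22 °C and T2 after 3 h of a 6 h ramp (38 °C). T3 was taken at the end of the ramp (45 °C) and T4 after another 90 min at 45 °C. T5 and T6 followed in acclimated plants 2 and 4 days later, back at 22 °C. On day 16 both kinds of plants were kept for 90 min at 45 °C. T7 and T8 are acclimated plants at the end of this shock and 2 days after it. T9, T10 and T11 are non-acclimated plants before it, at its end and 2 days after it. In units of 1e6, gene counts per library ran from 6.36 to 21.3 (median 9.53). The log2 levels of tubes of one plate correlated across genes with r of 0.912 to 0.990. For libraries of one time point in different batches r was 0.886 to 0.965. In every plate with a pair of tubes the tubes differed by more than sampling noise. All levels and changes rest on n = 2 plates per time point. Where genes passed, at least 98.9% had the same sign in both batches, which the test favours.

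In a principal component analysis the T3 and T4 plates stood apart on the first component, which held 38.5% of the variance, at scores of 139 to 190. On the second component (14.5%) the T7, T10 and T11 plates of batch 1 had the highest scores, 102 to 114, and those of batch 2 had 27.3 to 41.8.

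**Figure D1:**
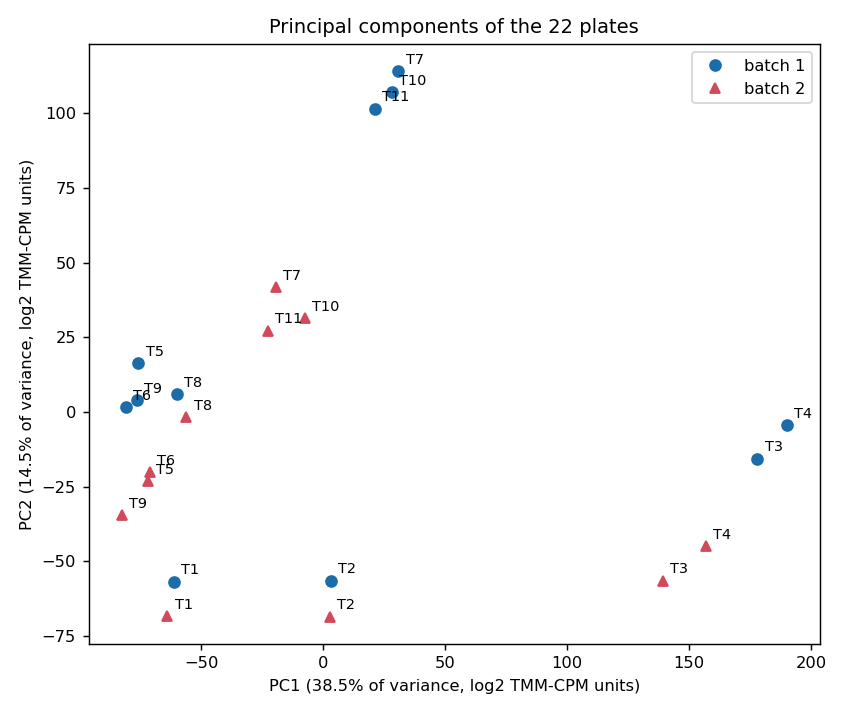
Scores of the 22 plates on the first and second principal components of log2 TMM-CPM, labelled by time point and coloured by batch, with batch 1 as circles and batch 2 as triangles. The T3 and T4 plates lie between 139 and 190 on the first component, apart from the rest.

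A set of 6 heat stress genes fixed in advance was followed throughout. They were HSP101 (AT1G74310), the disaggregase that resolves protein aggregates, and the transcription factor HSFA2 (AT2G26150). The others were the chloroplast small heat shock protein HSP21 (AT4G27670), the cytosolic small heat shock protein HSP18.2 (AT5G59720), the ascorbate peroxidase APX2 (AT3G09640) and the transcriptional coactivator MBF1C (AT3G24500). In TAIR10.1 they are protein-coding genes at 27936508 to 27940369 on chromosome 1 (HSP101, minus strand) and 11135624 to 11137792 on chromosome 2 (HSFA2, plus). HSP21 lies at 13818825 to 13819971 on chromosome 4 (minus) and HSP18.2 at 24062323 to 24063300 on chromosome 5 (plus). APX2 at 2956156 to 2958330 and MBF1C at 8918267 to 8919683 lie on chromosome 3 (plus).

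**Figure D2:**
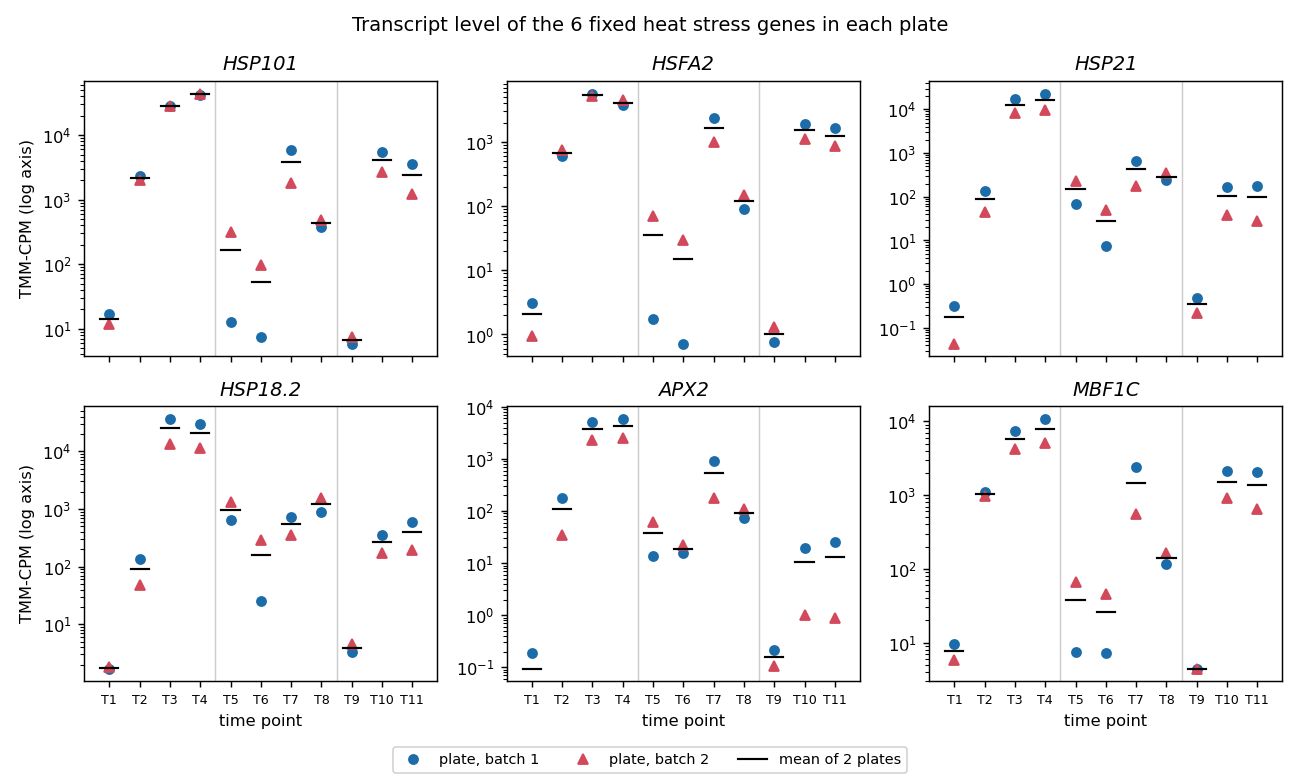
Level in TMM-CPM (log axis) of the 6 fixed genes at each time point, with a circle for the plate of batch 1, a triangle for that of batch 2 and a line at their mean. Vertical lines part acclimation days, later acclimated and non-acclimated samples. HSP101 rose from 14.3 ± 3.29 at T1 to 43369 ± 1195 TMM-CPM at T4, a log2 change of 11.55 with TMM, 9.67 with library size and 9.05 with the authors' scaling. The APX2 plate of batch 2 at T1, at 0 counts, is not drawn on the log axis.

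**Figure D3:**
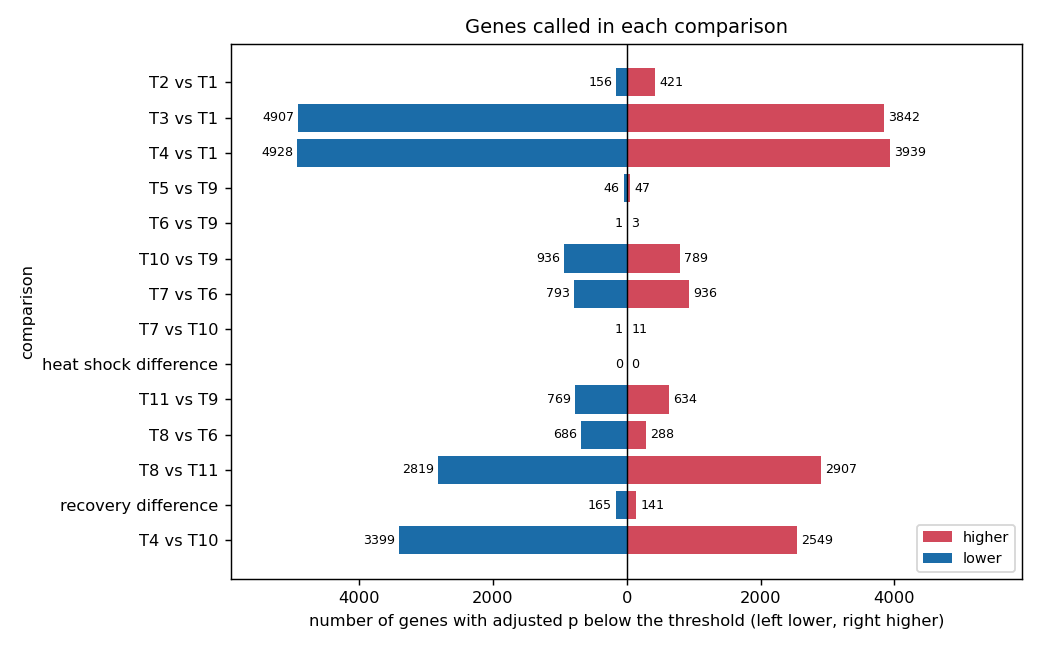
Number of genes that passed in each comparison fixed before the data were examined, higher in the first time point to the right of 0 and lower to the left. The numbers reach 8867 for T4 against T1, where the share of higher genes depends on the scaling, and 0 for the difference between the heat shock responses.

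The first comparison asked which transcripts had moved after 3 h of the ramp. At T2 small heat shock proteins of several compartments stood far above T1, led by the cytosolic HSP17.4 (AT3G46230, 10.8 ± 1.73) and HSP17.6II (AT5G12020, 10.07 ± 1.92) and the mitochondrial HSP23.6 (AT4G25200, 10.7 ± 2.19). Parentheses hold the log2 change and its error. HSP101 rose from 14.3 ± 3.29 to 2172 ± 184 TMM-CPM, HSFA2 rose by 8.22 and MBF1C by 7.08. HSP21 (8.76), HSP18.2 (5.64) and APX2 (9.85) rose as well. The transcripts that fell most were BT2 (AT3G48360, -4.21), a BTB and TAZ domain scaffold, GSTU1 (AT2G29490, -3.85), a glutathione transferase, and COL9 (AT3G07650, -3.73), a CONSTANS-like regulator. Of the small heat shock proteins, 15 of 16 rose (15 adjusted over the list alone) and 1 did not pass. Their median was 8.49 (by batch 7.64 and 8.03, adjusted p = 0.00487). Of the HSP70 and co-chaperone list, 20 of 24 rose (22 adjusted over the list alone) and 4 did not pass. Their median was 3.83 (by batch 3.88 and 3.84, adjusted p = 0.00284). Among them were the co-chaperone regulator BAG6 (AT2G46240, 7.59) and the immunophilin ROF2 (AT5G48570, 9.33). Of the heat memory genes, 8 of 15 rose (10 adjusted over the list alone) and 7 did not pass. Their median was 4.14 (by batch 4.17 and 4.07, adjusted p = 0.00484). In the endoplasmic reticulum, whose unfolded protein response raises folding enzymes, 13 of 17 rose (14 adjusted over the list alone) and 4 did not pass. Their median was 2.03 (by batch 1.9 and 2.17, adjusted p = 6.56e-04). Among them were the co-chaperone ERDJ3B (AT3G62600, 2.45) and the calnexin CNX1 (AT5G61790, 2.59). Heat stress transcription factors rose as a list (median 0.58, by batch 0.39 and 0.51, 0.97 with members at 0 at their bound, adjusted p = 0.0114): 7 of 22 rose (9 adjusted over the list alone) and 15 did not pass. HSFA7A (AT3G51910, 4.32) rose. The list call was lost with library size scaling (adjusted p = 0.0708). So was that of the jasmonic acid list (median 1.05, by batch 0.95 and 1.05, adjusted p = 0.0201, and 0.184 with library size). Of its members 0 of 9 passed and 4 rose adjusted over the list alone. The thermomorphogenesis list behaved alike (median 1.1, by batch 0.82 and 1.29, adjusted p = 0.0105, and 0.229 with library size): 1 of 9 rose (1 adjusted over the list alone) and 8 did not pass. Its growth regulator PIF4 (AT2G43010) rose by 2.94. The clock genes GI (AT1G22770, 3.89) and PRR7 (AT5G02810, 3.57) rose and the morning gene LHY (AT1G01060, -2.95) fell. T1 and T2 differed by 3 h in time of day. Of the clock list 2 of 14 rose and 1 fell (3 and 5 adjusted over the list alone) and 11 did not pass. Its directional test had an adjusted p of 0.783 and its mixed test 2.63e-07. In all, 577 of 20980 genes passed, 421 higher and 156 lower. Library size scaling turned the split to 288 higher and 598 lower and shifted the median of all genes to -0.49. Batch 1 and batch 2 alone called 5939 and 875, and these plates alone 2257. The count was 257 or 232 without T2 of batch 1 or 2 and 83 or 254 without T1 of batch 1 or 2. In these fits 8 to 19 of the 21 named genes and 2 to 6 of the 7 named lists that passed still did.

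T3 against T1 asked what had changed on reaching 45 °C. T1 and T3 differed by 6 h in time of day, so heat and hour cannot be parted. Among the named genes HSP21 rose most, by 16.02 ± 1.8 to 12944 ± 6716 TMM-CPM, followed by APX2 (15.21 ± 2.06) and HSP23.6 (14.6 ± 2.47). HSP101, HSFA2, HSP18.2 and MBF1C rose by 10.94, 11.28, 13.75 and 9.52. The falls were led by the early nodulin-like genes ENODL13 (AT5G25090, 229.7-fold lower, counting interval 41.1 to 9084) and ENODL15 (AT4G31840, 191-fold lower, counting interval 65.1 to 925) and the scaffold BT5 (AT4G37610, -7.24). Every tested member of the HSP70 and co-chaperone list rose (24 of 24, also adjusted over the list alone). Their median was 6.11 (by batch 5.91 and 6.15, adjusted p = 1.72e-04). Among small heat shock proteins 15 of 16 rose (15 adjusted over the list alone) and 1 did not pass. Their median was 12.78 (by batch 12.34 and 12.79, adjusted p = 5.15e-04). Among memory genes 13 of 15 rose (13 adjusted over the list alone) and 2 did not pass. Their median was 8.55 (by batch 7.32 and 6.35, adjusted p = 2.37e-04). In the unfolded protein response 15 of 17 rose (15 adjusted over the list alone) and 2 did not pass. Their median was 3.12 (by batch 2.86 and 3.03, adjusted p = 4.93e-05). Cell cycle genes fell as a list (median -2.0, by batch -1.79 and -1.53, adjusted p = 2.37e-04), with the mitotic cyclin CYCB1;2 (AT5G06150, -4.6) and the kinase CDKB2;1 (AT1G76540, -2.0). By gene, 13 of 16 fell (13 adjusted over the list alone) and 3 did not pass. Shoot apex markers also fell (0 up, 2 down and 1 not called of 3, 2 adjusted over the list alone, adjusted p = 0.0254). That call was lost with the authors' values (adjusted p = 0.357). Several lists rose with TMM but not with library size scaling. Heat stress transcription factors had 12 up, 2 down and 8 not called, 14 adjusted over the list alone. Their median was 2.13 (by batch 1.91 and 2.03, 2.91 with members at 0 at their bound, adjusted p = 0.00105, and 0.165 with library size). For abscisic acid and dehydration response there were 6 up, 1 down and 10 not called, 8 adjusted over the list alone. Their median was 1.08 (by batch 1.49 and 1.12, adjusted p = 0.0146, and 0.63 with library size). Reactive oxygen enzymes had 7 up, 1 down and 7 not called, 10 adjusted over the list alone. Their median was 1.77 (by batch 1.74 and 1.32, adjusted p = 0.00326, and 0.432 with library size). For photosynthesis there were 21 up, 0 down and 7 not called, 22 adjusted over the list alone. Their median was 2.04 (by batch 2.52 and 1.42, adjusted p = 0.0118, and 0.615 with library size), and -0.71 with the authors' values (adjusted p = 0.0911). Autophagy genes had a median of 0.81 with TMM and -0.79 with library size scaling (adjusted p = 4.65e-04 and 0.00119). They counted 6 up, 1 down and 5 not called, 7 adjusted over the list alone. Clock genes had a median of 0.38 with TMM and -1.18 with library size scaling (adjusted p = 0.017 and 0.0551). They counted 6 up, 3 down and 5 not called, 10 adjusted over the list alone. Jasmonic acid genes had a median of 1.15 with TMM and -0.41 with library size scaling (adjusted p = 0.0299 and 0.234). They counted 1 up, 0 down and 8 not called, 0 adjusted over the list alone. Ribosomal protein genes had a median of 0.80 with TMM and -0.80 with library size scaling (adjusted p = 0.0254 and 4.96e-04), and a downward test with the authors' values (adjusted p = 0.885). They counted 133 up, 10 down and 161 not called, 147 adjusted over the list alone. Of tested genes 8749 passed, 3842 higher and 4907 lower, against 761 and 14923 with library size scaling. That scaling moved the median of all genes from -0.24 to -1.82. The count was 5410 without T3 of batch 1 and 5081 without T1 of batch 1.

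T4 against T1 asked what had changed over the whole acclimation treatment. HSP21 went from 0.181 ± 0.195 to 16380.0 ± 9503 TMM-CPM, a log2 change of 16.34 ± 1.82. APX2 (15.38 ± 2.07), HSP23.6 (14.85 ± 2.49), HSP17.4 (14.67 ± 1.96), HSP17.6II (13.7 ± 2.16) and the endoplasmic HSP22.0 (AT4G10250, 14.71 ± 1.75) followed. HSP101 reached 43369 ± 1195 TMM-CPM (11.55), and HSP18.2 (13.48), HSFA2 (10.83) and MBF1C (9.97) rose with it. The falls were led by BT5 (368-fold lower, counting interval 65.9 to 14538) and ENODL13 (154-fold lower, counting interval 27.6 to 6106). The iron transporter IRT1 (AT4G19690, 105-fold lower, counting interval 29.1 to 871), the mitochondrial dicarboxylate carrier DIC2 (AT4G24570, 78.2-fold lower, counting interval 21.6 to 647), LHY (-6.77) and ENODL15 (-6.32) followed. IRT1 is a member of the root marker list. Of the small heat shock proteins 15 of 16 rose (15 adjusted over the list alone) and 1 did not pass. Their median was 13.05 (by batch 12.77 and 12.78, adjusted p = 5.19e-04). Of the HSP70 and co-chaperone list 24 of 24 rose and 24 rose adjusted over the list alone. Their median was 6.24 (by batch 5.99 and 6.28, adjusted p = 1.48e-04). Of memory genes 13 of 15 rose (13 adjusted over the list alone) and 2 did not pass. Their median was 8.83 (by batch 7.44 and 6.51, adjusted p = 2.60e-04). In the unfolded protein response list 15 of 17 rose (15 adjusted over the list alone) and 2 did not pass. Their median was 2.78 (by batch 2.71 and 2.81, adjusted p = 5.83e-05). Among them was CNX1 (3.59). Cell cycle genes fell (median -1.83, by batch -1.97 and -1.52, adjusted p = 2.60e-04), with CYCB1;2 (78.7-fold lower, counting interval 26.9 to 382). By gene, 12 of 16 fell (12 adjusted over the list alone) and 4 did not pass. Shoot apex markers fell (median -1.77, by batch -0.94 and -1.31, adjusted p = 0.0147, and 0.0972 with the authors' values). They counted 0 up, 2 down and 1 not called, 2 adjusted over the list alone.

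Another 8 lists rose at T4 with TMM scaling, and for each of them the call or the direction depended on the scaling. Of heat stress transcription factors 12 of 22 rose and 3 fell (12 and 3 adjusted over the list alone) and 7 did not pass. Their median was 1.95 (by batch 1.74 and 2.04, 3.08 with members at 0 at their bound, adjusted p = 0.0013, and 0.406 with library size). DREB2A (AT5G05410, 8.37) and DREB2B (AT3G11020, 6.39) were among those that rose. Of the abscisic acid and dehydration list 9 of 17 rose (10 adjusted over the list alone) and 8 did not pass. Their median was 2.19 (by batch 1.96 and 1.52, adjusted p = 0.00251, and 0.309 with library size). Among them were the galactinol synthase GOLS1 (AT2G47180, 11.93) and the dehydrin COR47 (AT1G20440, 3.96). Photosynthesis members stood higher (median 2.57, by batch 3.18 and 2.0, adjusted p = 0.0024), but not with library size scaling (adjusted p = 0.215) or the authors' values (median -0.61, adjusted p = 0.16): 24 of 28 rose (26 adjusted over the list alone) and 4 did not pass. For reactive oxygen enzymes 8 of 15 rose and 1 fell (8 and 1 adjusted over the list alone) and 6 did not pass. Their median was 1.48 (by batch 1.88 and 0.94, adjusted p = 0.00236), and -0.27 with library size scaling. Autophagy genes had a median of 0.79 with TMM and -1.08 with library size scaling, both past the threshold (adjusted p = 5.19e-04 and 4.65e-04): 6 of 12 rose (6 adjusted over the list alone) and 6 did not pass. For the clock the medians were 0.03 and -1.8 (adjusted p = 0.00967 and 0.0216). Of clock genes 6 of 14 rose and 2 fell (6 and 2 adjusted over the list alone) and 6 did not pass. For thermomorphogenesis the medians were 0.85 and -1.11 (adjusted p = 0.0321 and 0.0216): 3 of 9 rose (2 adjusted over the list alone) and 6 did not pass. In the jasmonic acid list 4 of 9 rose (4 adjusted over the list alone) and 5 did not pass. Their median was 2.0 (by batch 0.71 and 1.81, adjusted p = 0.00877), with a downward test under library size scaling (adjusted p = 0.36). The remaining lists did not pass, at adjusted p of 0.102 to 0.783.

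The T4 plates differed from T1 in 8867 of 20980 genes, 3939 higher and 4928 lower. With library size scaling 709 were higher and 16027 lower, and the median of all genes moved from -0.27 to -2.11. T1 was taken at dawn and T4 7.5 h later. By batch organelle genes held 0.203% and 0.811% of counts at T4 against 0.0543% and 0.0473%. Against T9, which was taken at the T4 hour on day 16, 9012 genes passed (3930 higher and 5082 lower, 710 and 15683 with library size). HSP21 (15.45) and HSP101 (12.67) rose against T9 too, and PIF4 did not pass there (0.58, adjusted p = 0.193). Of lists that passed against T1, those of abscisic acid (adjusted p = 0.179), the clock (0.217), jasmonic acid (0.95), thermomorphogenesis (0.199) and the shoot apex (0.0513) did not pass against T9, and with library size scaling all 5 fell. Leaving out a T1 plate, of batch 1 or 2, gave 5437 or 7220 genes. Leaving out a T4 plate gave 5898 or 6261. In these fits all 22 named genes and 12 to 13 of the 14 named lists still passed. Between T3 and T4, a comparison chosen after results had been seen, edgeR called 0 genes, with 1402 at an unadjusted p under 0.05, 12 by DESeq2 and 908 in the fit to these plates alone.

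**Figure D4:**
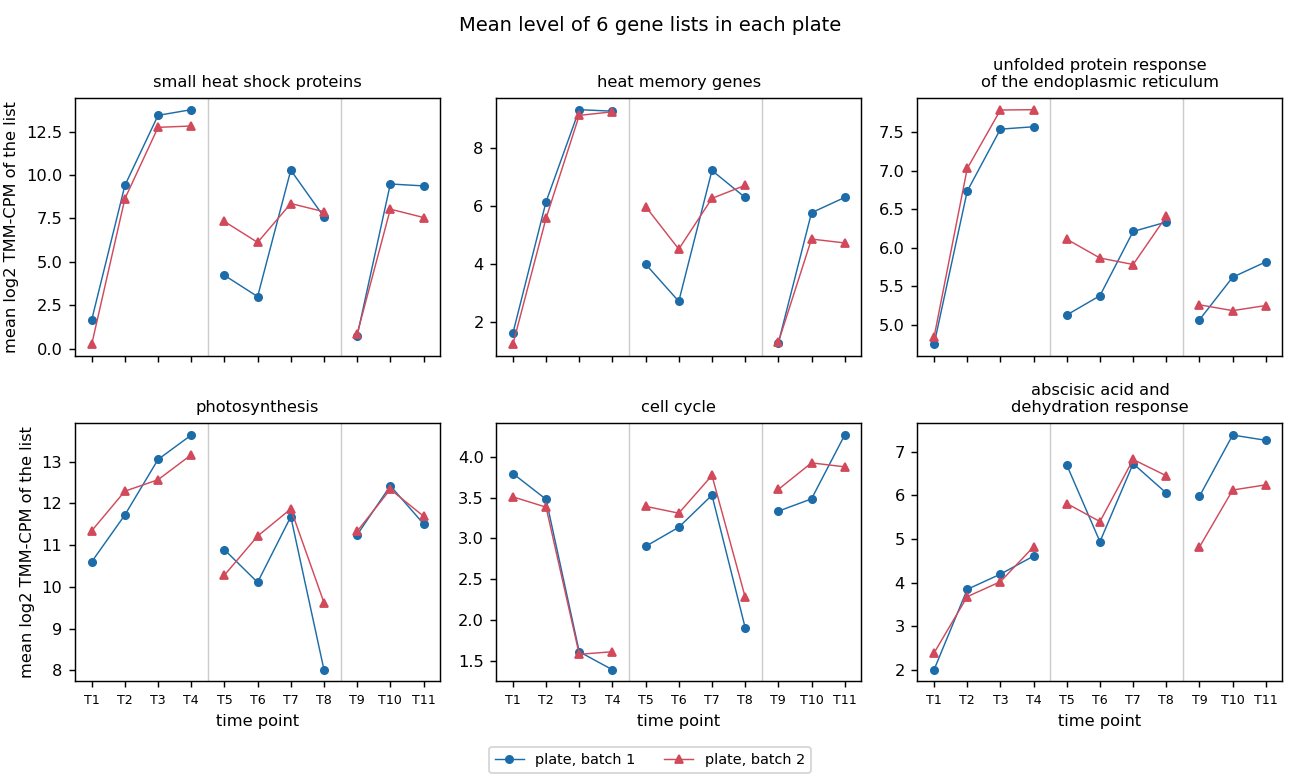
Mean log2 TMM-CPM of 6 gene lists in each plate by time point, with batch 1 as circles and batch 2 as triangles. Gaps part acclimation days, later acclimated and non-acclimated samples. The small heat shock protein list rose at T4 against T1 with every scaling (median 13.05 with TMM). The cell cycle list fell at T3 and T4 against T1 and at T8 against T6, while the photosynthesis rise at T4 was lost with library size scaling.

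Whether acclimated leaves still differed from never-heated leaves after 2 days was read from T5 and from T9, 2 days older. Several heat stress transcripts were far above T9 at T5, led by HSP22.0 (9.1 ± 1.46), HSP21 (9.05 ± 1.44) and the plastid protease FTSH6 (AT5G15250, 8.8 ± 1.54). By batch HSP22.0 rose by 6.14 and 9.44 and HSP21 by 6.1 and 8.31. HSP18.2 (8.0), APX2 (8.48) and HSP17.6C-CI (AT1G53540, 7.44) also rose. HSP101 (4.57, adjusted p = 0.172), HSFA2 (4.95, adjusted p = 0.193) and MBF1C (3.18, adjusted p = 0.255) did not pass. The root marker IRT1 (-6.38), the cytochrome P450 CYP82C4 (AT4G31940, 214-fold lower, counting interval 72.9 to 1039.8) and the dark-induced SEN1 (AT4G35770, -6.15, by batch -1.42 and -5.92) fell. As a list the heat memory genes rose (median 4.37, by batch 0.85 and 4.54, adjusted p = 0.0279), and by gene 5 of 15 rose (8 adjusted over the list alone) and 10 did not pass. The jasmonic acid list rose (median 1.64, by batch 1.66 and 1.13, adjusted p = 0.0279), where 0 of 9 passed and 7 rose adjusted over the list alone. Thermomorphogenesis genes fell (median -0.99, by batch -0.69 and -0.80, adjusted p = 0.0279), where 0 of 9 passed and 3 fell adjusted over the list alone. All these list calls were lost with library size scaling (adjusted p = 0.0618 for each) and not with the authors' values (0.00375 to 0.0055). Small heat shock proteins as a list did not pass (median 6.65, by batch 3.12 and 6.95, adjusted p = 0.0802, mixed 0.0156) but did with the authors' values (0.0055): 6 of 16 rose (14 adjusted over the list alone) and 10 did not pass. Over 21 members of this and the memory list abundant at T3, the T5 level above T9 in batch 2 was 1.09% to 13.0% of the T3 level. The other lists had adjusted p up to 0.996, and 7 of them, salicylic acid and autophagy included, passed the mixed test (adjusted p of 2.43e-04 to 0.0495). In all, 93 genes passed, 47 higher and 46 lower. Batch 1 and batch 2 alone called 4365 and 1129. Without 1 plate the count was 13 without T5 of batch 2 and 50 or 2 without T9 of batch 1 or 2. Over these fits 0 to 7 of the 9 named genes and 0 to 1 of the 3 named lists kept their call, and the fit to the T5 and T9 plates alone called 0.

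By day 16, when T6 and T9 were both taken before any heat shock, the question was what 4 days had left of the acclimation response. The malic enzyme NADP-ME1 (AT2G19900, 4.14 ± 0.62) and the expansin-like EXLB1 (AT4G17030, 1.46 ± 0.21) rose in acclimated leaves, and the ferric reductase FRO6 (AT5G49730, -2.99 ± 0.43) fell. The last gene that passed, AT1G11265, rose by 7.92, has no symbol and was chosen after its values were seen. Several heat stress transcripts were above T9 in both batches without passing. HSP21 stood at 28.5 ± 29.9 against 0.352 ± 0.192 TMM-CPM (6.75, adjusted p = 0.233). HSP18.2 (log2 change 5.45, adjusted p = 0.301) and APX2 (7.2, adjusted p = 0.34) were likewise higher. HSP101 differed by 0.31 in batch 1 and 3.62 in batch 2. Small heat shock proteins had a median of 5.4 (2.05 in batch 1 and 5.72 in batch 2, adjusted p = 0.303): 0 of 16 passed and 14 rose adjusted over the list alone. Of the memory genes 0 of 15 passed and 7 rose adjusted over the list alone. Their median was 2.92 (by batch 0.31 and 3.11, adjusted p = 0.303). In batch 2 the T6 level above T9 was 0.317% to 2.11% of the T3 level over 21 members of both lists that are abundant at T3. None of the 21 lists passed the directional test (adjusted p of 0.303 to 0.987), and the salicylic acid list passed the mixed test (adjusted p = 1.24e-04). The edgeR count was 4, 3 higher and 1 lower, with 1333 genes at an unadjusted p under 0.05 and 96 called by DESeq2. It was 5 higher and 0 lower with library size scaling (median 0.13) and 6 and 4 with the authors' values. Batch 1 and batch 2 alone called 3071 and 374, and these plates alone 744, and without any one of the T6 or T9 plates, in either batch, 0 passed.

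The heat shock response of plants without acclimation was read from T10 against T9. Heat stress transcription factors and chaperones led it. HSFA7B (AT3G63350) had 0 counts at T9 and was at least 1206-fold higher at T10. HSFA2 rose by 10.6 ± 1.86 and HSP101 by 9.3 ± 1.62 to 4121 ± 2026 TMM-CPM. The small heat shock proteins HSP17.6II (9.86), HSP17.6A (AT5G12030, 9.84) and HSP23.6 (9.55) rose with them. MBF1C (8.37), HSP21 (8.06), HSP18.2 (6.01) and APX2 (5.55, by batch 4.84 and 1.33) rose too. The falls were led by the pathogenesis-related PR1 (AT2G14610, -4.58, by batch -1.85 and -4.63) and PR4 (AT3G04720, -2.93), the chloroplast movement protein PMI2 (AT1G66840, -2.98), the zinc finger protein ZFP4 (AT1G66140, -2.94), the GDSL lipase-like GLL22 (AT1G54000, -2.71) and the xylosyltransferase XT1 (AT3G62720, -2.65). Of small heat shock proteins 15 of 16 rose (15 adjusted over the list alone) and 1 did not pass. Their median was 8.84 (by batch 8.75 and 7.45, adjusted p = 0.0103). Of the HSP70 and co-chaperone list 19 of 24 rose (24 adjusted over the list alone) and 5 did not pass. Their median was 3.57 (by batch 3.83 and 3.17, adjusted p = 0.00926). Among them were HOP3 (AT4G12400, 9.14) and BAG6 (7.29). Memory genes rose (median 4.44, by batch 4.03 and 2.03, adjusted p = 0.0144): 9 of 15 rose (10 adjusted over the list alone) and 6 did not pass. Transcription factors of heat stress rose as a list (median 0.26, by batch 0.36 and 0.07, the same with members at 0 at their bound, adjusted p = 0.0383), but with library size scaling the median was -0.37 and the call was lost (adjusted p = 0.177): 7 of 22 rose and 1 fell (8 and 2 adjusted over the list alone) and 14 did not pass. Autophagy genes rose (median 0.43, by batch 0.42 and 0.33, adjusted p = 0.0232), but with library size scaling the median was -0.24 (adjusted p = 0.244). Of them 0 of 12 passed and 0 passed adjusted over the list alone. The endoplasmic co-chaperone ERDJ3A (AT3G08970, 6.13) rose while the calreticulin CRT1A (AT1G56340, -2.16) and ERDJ3B (-1.02) fell. The unfolded protein response did not pass as a list (2 up, 2 down and 13 not called, 6 adjusted over the list alone, adjusted p = 0.946). Multi-aligned records were 13.2% and 38.2% at T10 by batch against 8.41% and 14.8% at T9, and organelle genes held 0.739% and 1.49% of counts against 0.137% and 0.0488%. Of tested genes 1725 passed, 789 higher and 936 lower. With library size scaling these were 300 and 4196 (median of all genes -0.69). Batches 1 and 2 alone called 11303 and 942, and these plates alone 593. Without single plates the counts were 201 or 751 without T10 of batch 1 or 2 and 75 or 371 without T9 of batch 1 or 2. In these fits 4 to 17 of the 21 named genes and 0 to 5 of the 5 named lists kept their call.

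The same shock in acclimated plants was read from T7 against T6. Heat stress transcription factors and chaperones led here too, with HSFA7A (7.93 ± 0.85), HSFA2 (7.06 ± 1.62) and HSP101 (6.31 ± 1.45). HSFA7B (6.21), the dehydration-responsive factor DREB2A (6.11) and the chaperone HSP70T-2 (AT2G32120, 6.07) also rose. HSP101 reached 3886 ± 2934 TMM-CPM. By batch HSFA2 rose by 10.89 and 5.09 and HSP101 by 9.57 and 4.2. MBF1C (5.63) rose, and HSP21 (3.36, adjusted p = 0.0708), APX2 (4.25, adjusted p = 0.0562) and HSP18.2 (1.6, adjusted p = 0.304) did not pass. Falls were led by TAS3 (AT3G17185, -4.69), a precursor of small interfering RNAs, LAC3 (AT2G30210, -3.9), a laccase, the beta-glucosidases BGLU21 (AT1G66270, -3.33) and BGLU22 (AT1G66280, -3.19), ZFP4 (-3.28) and OFP16 (AT2G32100, -3.1). Small heat shock proteins rose as a list (median 4.39, by batch 7.13 and 2.28, adjusted p = 0.0252), for example HSP15.7 (AT5G37670, 5.57). By gene, 7 of 16 rose (14 adjusted over the list alone) and 9 did not pass. HSP70 and co-chaperones also rose (median 3.14, by batch 4.04 and 2.03, adjusted p = 0.0169), among them BAG6 (6.04) and HSC70-5 (AT5G09590, 4.52). By gene, 19 of 24 rose (22 adjusted over the list alone) and 5 did not pass. Another 4 lists rose and lost their call with library size scaling, abscisic acid and autophagy also with the authors' values (adjusted p = 0.0802 for both). Of heat stress transcription factors 8 of 22 rose, 14 did not pass and 9 rose and 1 fell adjusted over the list alone. Their median was 0.47 (by batch 0.59 and 0.32, adjusted p = 0.0243), and -0.09 with library size scaling (adjusted p = 0.117). Of memory genes 6 of 15 rose (9 adjusted over the list alone) and 9 did not pass. Their median was 3.28 (by batch 4.86 and 1.78, adjusted p = 0.0243, and 0.0515 with library size). In the abscisic acid response 3 of 17 rose (10 adjusted over the list alone) and 14 did not pass. Their median was 1.42 (by batch 1.63 and 1.52, adjusted p = 0.0329, and 0.14 with library size). Of autophagy genes 1 of 12 rose (1 adjusted over the list alone) and 11 did not pass. Their median was 0.37 (by batch 0.31 and 0.40, adjusted p = 0.0329), and -0.31 with library size scaling (adjusted p = 0.158). Multi-aligned records were 5.12% and 21.7% at T7 by batch against 3.87% and 14.6% at T6, and organelle genes held 0.558% and 0.834% of counts against 0.0283% and 0.168%. In total 1729 genes passed, 936 higher and 793 lower. Of these, 590 rose and 503 fell in T10 against T9 as well. Independent lists of these sizes would share 35.2 and 35.4. Library size scaling gave 326 higher and 4046 lower (median of all genes -0.69). Fitted alone, batches 1 and 2 called 12396 and 786, and these plates alone 1034. Leaving out plates gave 54 without T7 of batch 1 and 23 or 197 without T6 of batch 1 or 2. Over these fits 3 to 15 of the 16 named genes and 0 to 4 of the 6 named lists kept their call.

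Acclimated and non-acclimated leaves were also compared directly at the end of the shock. The synaptotagmin SYTD (AT5G11100, 4.65 ± 0.74), the cell wall invertase CWINV5 (AT3G13784, 4.12 ± 0.64), NADP-ME1 (3.6 ± 0.60), the phosphodiesterase GDPD5 (AT1G74210, 1.88 ± 0.30), the lipase-like TLL1 (AT1G45201, 1.6 ± 0.26) and EXLB1 (1.51 ± 0.22) were higher in acclimated leaves. FRO6 (-2.65 ± 0.42) was lower. NADP-ME1, EXLB1 and FRO6 had also passed in the same direction before the shock. None of the 6 fixed heat stress genes passed. HSP101 stood at 3886 ± 2934 and 4121 ± 2026 TMM-CPM (-0.07, adjusted p = 0.997), HSP21 differed by 2.05 (adjusted p = 0.665) and APX2 by 5.9 (adjusted p = 0.218). None of the 21 lists passed the directional test (adjusted p of 0.293 to 0.943), and reactive oxygen enzymes passed the mixed test (adjusted p = 0.0342). Of the small heat shock proteins 0 of 16 passed and 0 passed adjusted over the list alone (median 0.42, by batch 0.59 and 0.07). Anthocyanin synthesis had the lowest p (median 1.95, by batch 1.69 and 2.85, adjusted p = 0.293), where 0 of 12 passed and 8 were higher adjusted over the list alone. Multi-aligned and organelle shares were lower at T7 than at T10 in both batches. Of 20980 genes 12 passed, 11 higher and 1 lower. At an unadjusted p under 0.05 there were 1636, and DESeq2 called 147. Batches 1 and 2 alone called 4397 and 258, and these plates alone 1751, and library size scaling shifted the median to 0.12. Fits without 1 plate gave 0 without T7 of batch 1 and 2 or 0 without T10 of batch 1 or 2.

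Whether acclimation changed the heat shock response itself was tested as the difference between T7 against T6 and T10 against T9. The differences in HSP21 (-4.69 ± 1.56), HSP18.2 (-4.42 ± 1.39), HSP101 (-2.99 ± 1.66) and HSFA2 (-3.54 ± 1.85) had an adjusted p of 1 each and did not pass. By batch the HSP101 difference was -0.21 in batch 1 and -4.19 in batch 2. Small heat shock proteins had a median difference of -4.5 (-1.1 in batch 1 and -5.15 in batch 2, adjusted p = 0.985). Of them 0 of 16 passed and 12 were lower adjusted over the list alone. For HSP70 and co-chaperones it was -0.52 (0.08 and -1.18, adjusted p = 0.985), where 0 of 24 passed and 0 passed adjusted over the list alone. In batch 2 the T6 baseline of this test stood above T9 by a median of 5.72 over small heat shock proteins. No list passed (adjusted p of 0.985 to 0.996). EdgeR called 0 genes, with 189 at an unadjusted p under 0.05. DESeq2 and the authors' values called 0 and 0, as did every fit without 1 of the plates compared. Batches 1 and 2 alone, with tubes as replicates, called 120 and 26.

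Recovery without acclimation was read from T11 against T9, also 2 days apart in age. With tubes as replicates T11 and T10 differed in 5719 genes in batch 1 and 1 in batch 2, which bears on every use of T11. Heat stress transcripts were above T9. HSFA7B was at least 1043-fold higher than at T9, where it had 0 counts. HSFA2 (10.33 ± 1.84), HSP17.6A (9.36), HSP17.6II (9.29), HSP23.6 (9.11) and HSP22.0 (8.92) rose. HSP101 (8.54) stood at 2421 ± 1669 TMM-CPM, and MBF1C (8.19), HSP21 (7.96), HSP18.2 (6.58) and APX2 (5.85, by batch 5.21 and 1.17) rose. Falls were led by PR1 (-5.77, by batch -2.29 and -5.01), CYP82C4 (-4.08), BT2 (-3.56, by batch -0.51 and -4.43), the leaf phase regulator SPL9 (AT2G42200, -3.32), the beta-glucosidase BGLU33 (AT2G32860, -3.23) and the root marker IRT1 (-3.18). Of small heat shock proteins 15 of 16 rose (15 adjusted over the list alone) and 1 did not pass. Their median was 8.73 (by batch 8.57 and 6.55, adjusted p = 0.00939). Of HSP70 and co-chaperones 18 of 24 rose (21 adjusted over the list alone) and 6 did not pass. Their median was 2.92 (by batch 3.44 and 2.27, adjusted p = 0.00939). Of memory genes 10 of 15 rose (11 adjusted over the list alone) and 5 did not pass. Their median was 5.67 (by batch 4.27 and 1.75, adjusted p = 0.00939). The heat stress transcription factor list rose (median 0.83, by batch 1.12 and 0.10, the same with members at 0 at their bound, adjusted p = 0.0392, and 0.0604 with library size): 7 of 22 rose and 1 fell (8 and 2 adjusted over the list alone) and 14 did not pass. Vascular markers fell (median -0.97, by batch -1.17 and -0.69, adjusted p = 0.0392), among them the sucrose transporter SUC2 (AT1G22710, -1.46). By gene, 2 of 6 fell (3 adjusted over the list alone) and 4 did not pass. Multi-aligned records were 19.2% and 35.0% at T11 by batch against 8.41% and 14.8% at T9, and organelle genes held 1.24% and 0.949% of counts against 0.137% and 0.0488%. Against T9 1403 genes passed, 634 higher and 769 lower. Library size scaling gave 296 and 1299 (median of all genes -0.41). Fitted alone, batches 1 and 2 called 11657 and 924, and these plates alone 253. Without single plates the counts were 131 without T11 of batch 1 and 117 or 272 without T9 of batch 1 or 2. Across them 3 to 15 of the 18 named genes and 0 to 4 of the 5 named lists kept their call.

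In acclimated plants T8 was compared with T6, 2 days younger, so shock and age cannot be parted. Falls were led by the beta-glucosidase BGLU21 (-9.0), the proline-rich cell wall protein PRP3 (AT3G62680, -6.81) and the germin-like GER3 (AT5G20630, -4.13). The light-harvesting protein LHCB2.3 (AT3G27690, -3.58), the peroxidase RCI3 (AT1G05260, -3.55) and BGLU22 (-3.52) followed. Rises were led by the nitrate transporter NRT1.8 (AT4G21680, 5.86, by batch 6.83 and 1.62), the cell wall enzyme XTH23 (AT4G25810, 5.58, by batch 6.68 and 1.44) and the expansin-like EXLA1 (AT3G45970, 4.68, by batch 5.77 and 0.36). The proline dehydrogenase ERD5 (AT3G30775, 4.48, by batch 5.88 and 0.27), ABR1 (AT5G64750, 4.49) and FTSH6 (4.43) followed. None of the 6 fixed heat stress genes passed, among them HSP101 (3.08, adjusted p = 0.162) and HSP21 (3.14, adjusted p = 0.103). Photosynthesis genes fell as a list (median -1.81, by batch -2.0 and -1.64, adjusted p = 0.0135), among them PSAK (AT1G30380, -2.23) and LHCB2.1 (AT2G05100, -2.61). By gene, 4 of 28 fell (25 adjusted over the list alone) and 24 did not pass. Cell cycle genes fell (median -1.14, by batch -1.15 and -0.91, adjusted p = 0.00582), with KN (AT1G08560, -1.69), a syntaxin of cytokinesis. By gene, 4 of 16 fell (11 adjusted over the list alone) and 12 did not pass. Root markers, which had risen from T5 to T6, fell. Their median was -2.95 (by batch -1.23 and -1.93, the same with members at 0 at their bound, adjusted p = 0.00582). The root hair genes RHD6 (AT1G66470) and COBL9 (AT5G49270) had 0 counts at T8, at least 21.1-fold and 37.2-fold lower. By gene, 4 of 12 fell (9 adjusted over the list alone) and 8 did not pass. Thermomorphogenesis genes fell (median -1.14, by batch -0.87 and -0.83, adjusted p = 0.00582), with PIF4 (-1.4). By gene, 3 of 9 fell (4 adjusted over the list alone) and 6 did not pass. Guard cell and stomatal lineage markers fell (median -1.68, by batch -0.98 and -1.55, adjusted p = 0.0135, and 0.0531 with library size), with SPCH (AT5G53210, -2.58) and MUTE (AT3G06120, -3.13). By gene, 2 of 5 fell (2 adjusted over the list alone) and 3 did not pass. Heat stress transcription factors rose (median 1.17, by batch 0.98 and 1.38, adjusted p = 0.0121), with HSFA7A (4.18) and HSFA3 (AT5G03720, 4.0). By gene, 5 of 22 rose (7 adjusted over the list alone) and 17 did not pass. Memory genes also rose (median 3.04, by batch 3.74 and 2.29, adjusted p = 0.0121): 3 of 15 rose (9 adjusted over the list alone) and 12 did not pass. Multi-aligned records were 7.25% and 21.2% at T8 by batch and organelle genes held 0.429% and 0.636% of counts, all above T6. Of tested genes 974 passed, 288 higher and 686 lower. Batches 1 and 2 alone called 10190 and 1510, and these plates alone 605. Leaving out plates gave 87 without T8 of batch 1 and 300 or 221 without T6 of batch 1 or 2. Through these 5 to 13 of the 22 named genes and 3 to 6 of the 7 named lists kept their call.

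How both kinds of leaves differed 2 days after the shock was read from T8 against T11. The alpha-amylase AMY1 (AT4G25000, 7.4 ± 1.06), the phosphate-induced PHI-1 (AT1G35140, 7.22), XTH23 (6.83), CWINV5 (6.64 ± 0.70), EXLA1 (6.52) and the jasmonate-regulated oxygenase JRG21 (AT3G55970, 6.32) were higher in acclimated leaves. Lower in acclimated leaves were the defensins PDF1.2 (AT5G44420, -6.48, by batch -0.07 and -6.06), PDF1.2c (AT5G44430, -6.27, by batch -0.15 and -5.22) and PDF1.3 (AT2G26010, -5.78, by batch -0.15 and -5.23). So were the chlorophyll synthesis enzyme PORA (AT5G54190, -5.67, by batch -1.51 and -4.85), LHCB2.3 (-4.81 ± 0.71) and the thionin THI2.2 (AT5G36910, -4.79 ± 0.89). MBF1C (-3.18) was lower and APX2 (3.65, adjusted p = 0.0491) higher. HSP101 (-2.55, adjusted p = 0.126), HSFA2 (-3.47, adjusted p = 0.069) and HSP21 (1.93, adjusted p = 0.177) did not pass. Photosynthesis genes were lower as a list (median -2.81, by batch -3.56 and -2.25, adjusted p = 0.00221), for example PSAK (-3.69) and RBCS3B (AT5G38410, -2.6). By gene, 26 of 28 were lower (28 adjusted over the list alone) and 2 did not pass. Cell cycle genes were lower too (median -2.17, by batch -2.31 and -1.39, adjusted p = 1.14e-04), with KN (-3.2) and CYCB1;2 (-2.57). By gene, 14 of 16 were lower (15 adjusted over the list alone) and 2 did not pass. Thermomorphogenesis genes were lower (median -2.16, by batch -0.52 and -1.38, adjusted p = 0.0025, and 0.0699 with library size), with EXPA8 (AT2G40610, -4.68). By gene, 5 of 9 were lower (5 adjusted over the list alone) and 4 did not pass. The unfolded protein response was higher as a list (median 0.97, by batch 0.98 and 0.83, adjusted p = 0.0228), with CRT1A (2.32) and BIP3 (AT1G09080, 3.15). By gene, 8 of 17 were higher and 1 was lower (11 and 1 adjusted over the list alone) and 8 did not pass. Senescence and chlorophyll breakdown genes were higher (median 0.89, by batch 0.79 and 0.31, adjusted p = 0.0228): 5 of 15 were higher and 1 was lower (5 and 1 adjusted over the list alone) and 9 did not pass. Heat stress transcription factors went both ways (adjusted p = 0.843, mixed test 5.43e-05): 4 of 22 were higher and 5 were lower (4 and 6 adjusted over the list alone) and 13 did not pass, HSFA7A (-4.4) and DREB2A (-3.05) being lower and HSFA1A (AT4G17750, 1.75) higher. Multi-aligned and organelle shares were lower at T8 than at T11 in both batches. In all 5726 genes passed, 2907 higher and 2819 lower. With library size scaling these were 5376 and 1228 (median of all genes 0.54). Fitted alone, batches 1 and 2 called 13377 and 4739, and these plates 0. Fits without 1 plate gave 1654 without T8 of batch 1 and 2967 or 3302 without T11 of batch 1 or 2. Across these fits 16 to 22 of the 24 named genes and 3 to 4 of the 5 named lists kept their call.

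Whether acclimation changed the response 2 days after the shock was tested as (T8 against T6) minus (T11 against T9). The difference was higher in acclimated plants for EXLA1 (6.55 ± 1.46), the lipid transfer protein AZI1 (AT4G12470, 5.67), PR4 (3.9), TPS11 (AT2G18700, 3.88) and the SBP transcription factor SPL2 (AT5G43270, 3.78). It was lower for BGLU21 (-4.98 ± 1.16), HSFA7A (-4.34 ± 0.98), the splicing factor SR45a (AT1G07350, -3.69), LSU2 (AT5G24660, -3.18) and the cytochrome P450 CYP77B1 (AT1G11600, -3.16). Cell cycle genes had a lower response in acclimated plants as a list (median -1.87, by batch -1.96 and -1.05, adjusted p = 0.00337, and 0.0567 with library size), with KN (-2.8), PCNA1 (AT1G07370, -2.41) and CYCB1;2 (-2.03). By gene, 3 of 16 were lower (13 adjusted over the list alone) and 13 did not pass. Of the small heat shock proteins 1 of 16 was lower (15 adjusted over the list alone) and 15 did not pass. Their median was -5.84 (by batch -3.99 and -4.89, adjusted p = 0.128). HSP15.7 (-6.23 ± 1.11) was the one that passed. Of photosynthesis genes 0 of 28 passed and 18 were lower adjusted over the list alone. Their median was -2.19 (by batch -2.48 and -2.07, adjusted p = 0.0905). The 6 fixed genes did not pass, the nearest being MBF1C (-5.84, adjusted p = 0.0584) and HSFA2 (-7.18, adjusted p = 0.0687). In all 306 genes passed, 141 with a higher and 165 with a lower difference. Library size scaling gave 130 and 39 (median 0.40). Batches 1 and 2 alone called 10454 and 674. Without single plates the counts were 6 or 744 without T8 of batch 1 or 2, 101 or 7 without T6 of batch 1 or 2, 10 or 176 without T11 of batch 1 or 2 and 0 or 0 without T9 of batch 1 or 2. Over them 0 to 10 of the 14 named genes and the cell cycle list in each case kept their call. The fit without other time points called 0, and leaving out the second T6 tube of batch 2, chosen after seeing the data, gave 182.

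The slow and the sudden exposure were compared at their ends, T4 against T10, both after 90 min at 45 °C but at different ages. APX2 (9.09 ± 1.6), HSP21 (7.4 ± 1.3), HSP18.2 (6.28) and the gibberellin-regulated GASA1 (AT1G75750, 6.86 ± 1.11) were higher after the slow exposure. HSP101 (3.37, adjusted p = 0.0554), HSFA2 (1.37, adjusted p = 0.435) and MBF1C (2.39, adjusted p = 0.0895) did not pass. Lower were AT14A (AT3G28290, -11.43, by batch -0.15 and -6.04), a membrane protein, and PORA (281-fold lower, counting interval 50.3 to 11110.0), whose differences by batch were -0.63 and -6.28. UF3GT (AT5G54060, 327-fold lower, counting interval 112 to 1586), of anthocyanin synthesis, was lower as well. Small heat shock proteins were higher (median 4.61, by batch 4.31 and 5.17, adjusted p = 0.0254, and 0.158 with the authors' values), where 13 of 16 were higher (15 adjusted over the list alone) and 3 did not pass. HSP70 and co-chaperones were higher (median 2.28, by batch 1.79 and 2.85, adjusted p = 0.0101, and 0.158 with the authors' values): 17 of 24 were higher (20 adjusted over the list alone) and 7 did not pass. Memory genes were higher too (median 4.04, by batch 3.63 and 4.04, adjusted p = 0.00603): 10 of 15 were higher (11 adjusted over the list alone) and 5 did not pass. The unfolded protein response was higher (median 2.29, by batch 1.78 and 2.81, adjusted p = 9.19e-05), with CRT1A (3.73). By gene, 13 of 17 were higher (15 adjusted over the list alone) and 4 did not pass. Abscisic acid and dehydration genes were lower (median -2.88, by batch -2.93 and -1.56, adjusted p = 0.0127), for example COR15A (AT2G42540, -5.3) and RD29A (AT5G52310, -4.87). By gene, 1 of 17 was higher and 9 were lower (1 and 10 adjusted over the list alone) and 7 did not pass. Cell cycle genes were lower (median -1.98, by batch -1.68 and -1.76, adjusted p = 3.62e-04): 13 of 16 were lower (13 adjusted over the list alone) and 3 did not pass. Autophagy genes were higher with TMM scaling and lower with library size scaling (medians 0.20 and -0.89, adjusted p = 0.0101 and 0.00974): 4 of 12 were higher, 8 did not pass and 4 were higher and 1 was lower adjusted over the list alone. Multi-aligned and organelle shares were lower at T4 in both batches. Of tested genes 5948 passed, 2549 higher and 3399 lower. With library size scaling these were 627 and 10772, and the scaling moved the median of all genes from -0.17 to -1.24. The fit to these plates alone called 3530, batch 1 alone 10205 and batch 2 alone 5965. Leaving out plates gave 3521 or 3520 without T4 of batch 1 or 2 and 3626 without T10 of batch 2. In them 8 to 10 of the 10 named genes and 4 to 7 of the 7 named lists kept their call.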

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

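The tests of a labelling error, carry-over, read assignment and a single library were chosen after their results were seen. Those of the number of replicates, decline, abundant genes and depth were written before.

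The first pattern was that non-acclimated leaves 2 days after the shock resembled those at its end, with 0 genes called between T11 and T10 by edgeR, 1461 at an unadjusted p under 0.05, 38 called by DESeq2 and 1346 in the fit to these plates alone. Whether the number of plates is the whole cause cannot be told. At the same size 5167 genes were called between T8 and T7. The difference between both changes called 128, past the bound of 20 set before. For it DESeq2 called 1211, the authors' values 463, library size scaling 11 and the fit without other time points 0. Tubes of T11 taken from the T10 plate were argued against in batch 1, where 5719 genes differed between T11 and T10 with tubes as replicates, but such an error remains possible in batch 2, where 1 gene differed against 2787 between T8 and T7, and would put end-of-shock leaves into that batch of T11/T9, T8/T11 and the recovery difference. The batches were judged apart, and the bound of 20 was asked of the other scaling, only after the counts were seen. Whether heat stress transcripts declined further in acclimated leaves could not be told (adjusted p = 0.613 for HSP70 and co-chaperones, median -1.3, -2.21 in batch 1 and -0.21 in batch 2, and 0.671 for small heat shock proteins, median -1.48, -2.76 and -0.01), so slower recovery without acclimation stays an open hypothesis.

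The second pattern was the level of heat stress transcripts above T9 at T5 and T6, 2 and 4 days after acclimation, at T6 with a median of 5.4 over small heat shock proteins that did not pass. Heated RNA carried over would give all genes about one share of the heated level. In batch 1 the 90th percentile of the shares was at least 55.8-fold the 10th at T6 and 27.6-fold at T5. This argues against the sources tried, T3, T4, T7 and T10. In batch 2 the lowest ratio was 2.57 at T6 (source T3), so tissue or RNA of a heated plate may have entered those tubes. At T5 it was 4.17 (source T4), between the bounds of 3 and 5, so it cannot be told. Transcripts that persist at equal rates would give the same values. The measure replaced the highest over the lowest share (6.66) after the shares were seen. Reads assigned to the wrong library after library preparation were argued against in the T5 and first T6 libraries of batch 2, where the ribosomal RNA locus AT2G01010 stood at up to 1.3 CPM and 12.9 was needed, but not in the second T6 library, whose 18199 CPM passed that of every T3 and T4 library of that batch; without that tube the median was 5.35, which argues against it alone as the cause. A lasting effect of acclimation stays open beside carry-over, which in batch 2 would also lower T7/T6, T8/T6 and both differences.

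The third pattern was that the direction of change at T4 depended on the scaling. The 100 most abundant genes at T4 held 59.4% of its counts and 18% of those at T1, and without them the median change with library size scaling was -1.02 instead of -2.03 (means of both batches' medians, not fitted). The bound set beforehand was -1, between the batches' -1.17 and -0.87, so whether a few abundant genes account for the pattern cannot be told. That both batches must pass it was set after the value was seen. At equal total depth T4 had counts at 88.6% as many loci as T1, under the bound of 90 set before. By batch 19420 loci stood against 22111 and 19456 against 21768. These values argue against lower total depth alone as the cause of fewer loci. That share was 91.3% without the abundant genes and with the rest at equal depth, a test added later. A true fall of most transcripts relative to the total was not tested, as no spike-in was used here.

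Other values stood out without an explanation being weighed. The difference between the recovery responses called 306 genes and the cell cycle list (adjusted p = 0.00337), with EXLA1 (6.55), AZI1 (5.67), PR4 (3.9), TPS11 (3.88) and SPL2 (3.78) higher in acclimated plants. BGLU21 (-4.98), HSFA7A (-4.34), SR45a (-3.69), LSU2 (-3.18) and CYP77B1 (-3.16) were lower. Among the 4 libraries of a time point, the second tube of T1 in batch 1 had HSFA2 at 4.31 TMM-CPM (0.754 to 1.27 in the others). HSP21 stood at 423 TMM-CPM (236 to 259.5 in the others) in the second T8 tube of batch 2. It stood at 1.01 TMM-CPM (0.110 to 0.235 in the others) in the second T9 tube of batch 1. In that T9 library organelle genes held 0.241% of counts (0.0309 to 0.0668 in the others). The second T2 tube of batch 2 had a TMM factor of 0.750 (1.1 to 1.16 in the others), with its 10 most abundant genes at 16.2% of counts (10.4 to 11.0 in the others). For the second T6 tube of batch 2 that share was 14.1% (5.83 to 6.29 in the others). Over 100 groups and measures these were 7 such values, where chance gives about 5. Records aligned to more than 1 place, which no comparison used, were 27.1% on average at T11, where the unheated T1 and T9 libraries reached 12.5% in batch 1 and 16.5% in batch 2.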

How the results depend on the processing

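Alternatives chosen after seeing the data were the authors' values and the data without the second T6 tube of batch 2 or organelle genes. The others were set before. Of 210 named gene results that passed, 58 did so in the same direction in every alternative, and of 81 list results 6. Over all alternatives of named genes 3595 values stayed on their side of the threshold, 623 lost it, 125 came to pass and 8 changed direction, and for lists the numbers were 1116, 253, 0 and 16. Of 220 list results that did not pass in the 14 fixed comparisons alone, 138 did in at least 1 alternative, 10 in both directions. With 2 plates per time point most 2-fold changes could not be detected, and each plate is also a batch of its time point. The cause of the changes below was not tested.

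With library size scaling the count of genes was 886 for T2/T1, 15684 for T3/T1, 16736 for T4/T1, 4496 for T10/T9, 4372 for T7/T6, 169 for the recovery difference and 11399 for T4/T10. List tests turned downward there, with adjusted p 0.432 for reactive oxygen enzymes, 0.00119 for autophagy, 0.0551 for the clock, 0.234 for jasmonic acid and 4.96e-04 for ribosomal proteins at T3/T1. At T4/T1 it was 0.141 for reactive oxygen enzymes, 4.65e-04 for autophagy, 0.0216 for the clock, 0.0216 for thermomorphogenesis and 0.36 for jasmonic acid. For autophagy it was 0.244 at T10/T9, 0.158 at T7/T6 and 0.00974 at T4/T10. The log2 change was 0.00864 for HSP101 in T7/T10. With the authors' values the count was 217 for T5/T9, 10 for T6/T9, 1842 for T8/T6 and 677 for the recovery difference. List tests turned downward with adjusted p 0.0911 for photosynthesis and 0.885 for ribosomal proteins at T3/T1. For photosynthesis it was 0.16 at T4/T1. The log2 change was 0.0850 for HSP101 in T7/T10. Over all alternatives the adjusted p of these lists ran from 9.17e-11 to 0.885. DESeq2's Wald test called 1175 for T2/T1, 515 for T5/T9, 96 for T6/T9, 3402 for T10/T9, 3356 for T7/T6, 147 for T7/T10, 3222 for T11/T9, 2142 for T8/T6 and 1955 for the recovery difference. Without the filter on low counts the count was 7 for T6/T9, and without the second T6 tube of batch 2 it was 182 for the recovery difference. Without a batch term it was 339 for T2/T1, 17 for T5/T9, 0 for T6/T9, 600 for T10/T9, 570 for T7/T6, 0 for T7/T10, 478 for T11/T9, 356 for T8/T6, 3506 for T8/T11 and 13 for the recovery difference. Fits to the plates compared alone called 2257 for T2/T1, 0 for T5/T9, 744 for T6/T9, 593 for T10/T9, 1034 for T7/T6, 1751 for T7/T10, 253 for T11/T9, 605 for T8/T6, 0 for T8/T11, 0 for the recovery difference and 3530 for T4/T10.

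Tubes as replicates measure only the spread within a plate, and called 2520 for T2/T1, 1259 for T5/T9, 501 for T6/T9, 6320 for T10/T9, 6298 for T7/T6, 852 for T7/T10, 2 for the heat shock difference, 6443 for T11/T9, 4740 for T8/T6, 9668 for T8/T11, 5507 for the recovery difference and 8962 for T4/T10. With the plate as a random effect the counts were 1195 for T2/T1, 489 for T5/T9, 70 for T6/T9, 3626 for T10/T9, 3525 for T7/T6, 79 for T7/T10, 3469 for T11/T9, 2566 for T8/T6 and 2083 for the recovery difference. In batch 1 alone they were 5939 for T2/T1, 4365 for T5/T9, 3071 for T6/T9, 11303 for T10/T9, 12396 for T7/T6, 4397 for T7/T10, 120 for the heat shock difference, 11657 for T11/T9, 10190 for T8/T6, 13377 for T8/T11, 10454 for the recovery difference and 10205 for T4/T10, and log2 changes were 0.12 for HSP101 in T7/T10 and 0.37 for HSFA2 in the heat shock difference. In batch 2 alone they were 875 for T2/T1, 1129 for T5/T9, 374 for T6/T9, 942 for T10/T9, 786 for T7/T6, 258 for T7/T10, 26 for the heat shock difference, 924 for T11/T9, 1510 for T8/T6 and 674 for the recovery difference.

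Tubes share only a number across time points. Deviations of tubes with the same number correlated at -0.12 to 0.16 (median 0.0342) over 45 pairs of plates in batch 1 and at -0.23 to 0.41 (median 0.0778) over 55 pairs in batch 2. A block for the tube number, with tubes as replicates, gave 2595 for T2/T1, 1289 for T5/T9, 482 for T6/T9, 6461 for T10/T9, 6465 for T7/T6, 892 for T7/T10, 2 for the heat shock difference, 6618 for T11/T9, 4818 for T8/T6, 9814 for T8/T11, 5624 for the recovery difference and 9052 for T4/T10.

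Leaving out each plate in turn changed the counts to 83 to 257 for T2/T1, 5081 to 6978 for T3/T1, 5437 to 7220 for T4/T1, 2 to 95 for T5/T9, 0 for T6/T9, 75 to 751 for T10/T9, 23 to 2160 for T7/T6, 0 to 12 for T7/T10, 117 to 1139 for T11/T9, 87 to 829 for T8/T6, 1654 to 4352 for T8/T11, 0 to 744 for the recovery difference and 3520 to 4333 for T4/T10. Log2 changes ran from -1.45 to 0.77 for HSP101 in T7/T10, -4.67 to 0.64 for HSFA2 in the heat shock difference and -0.43 to 9.92 for XTH33 in T8/T7.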

Other observations

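All comparisons given here were chosen after results had been seen. From the end of the shock to 2 days later, acclimated leaves (T8 against T7) gained the cell wall enzyme XTH33 (AT1G10550, 8.52, by batch 7.05 and 0.06), PHI-1 (6.97) and ABR1 (6.78). Acclimated leaves lost the light-harvesting LHCB2.3 (-4.72), the seed storage protein SESA5 (AT5G54740, -4.6) and the root marker IRT1 (-4.59). XTH33 did not keep its rise without T8 of batch 1 (-0.43, adjusted p = 0.896). Photosynthesis genes fell as a list (median -2.81, by batch -3.58 and -2.31, adjusted p = 0.0013), where 27 of 28 fell (28 adjusted over the list alone) and 1 did not pass. Cell cycle genes fell (median -1.65, by batch -1.46 and -1.32, adjusted p = 6.17e-04), where 12 of 16 fell (14 adjusted over the list alone) and 4 did not pass. Thermomorphogenesis genes fell (median -1.72, by batch -1.33 and -1.07, adjusted p = 0.00265, and 0.138 with library size): 5 of 9 fell (5 adjusted over the list alone) and 4 did not pass. Root markers fell (median -2.14, by batch -0.98 and -0.72, the same with members at 0 at their bound, adjusted p = 0.0436, 0.129 with library size scaling and 0.0516 with the authors' values): 3 of 12 fell (7 adjusted over the list alone) and 9 did not pass. Shoot apex markers rose (median 1.99, by batch 0.84 and 1.07, adjusted p = 0.0316, and 0.085 with the authors' values), where 2 of 3 rose (2 adjusted over the list alone) and 1 did not pass. In all 5167 genes passed, 2518 higher and 2649 lower, against 6589 and 917 with library size scaling (median of all genes 0.70). Batches 1 and 2 alone called 13622 and 2787, these plates alone 3212, and leaving out plates gave 804 without T8 of batch 1 and 1015 without T7 of batch 1.

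The change from the end of the shock to 2 days later was also compared between acclimated and non-acclimated plants. It was higher in acclimated plants for SPL2 (3.6) and the meristem regulators HAM1 (AT2G45160, 2.6) and HAM3 (AT4G00150, 2.55), and lower for CYP77B1 (-3.8) and the growth regulator AN3 (AT5G28640, -3.23). Cell cycle genes were lower as a list (median -2.11, by batch -2.36 and -1.43, adjusted p = 0.00153, and 0.0748 with library size): 5 of 16 were lower (14 adjusted over the list alone) and 11 did not pass. This test called 128 genes, 34 higher and 94 lower. These were 6 and 5 with library size scaling (median of all genes 0.39) and 174 and 289 with the authors' values. The fit to these plates alone called 0. Leaving out plates gave 1 or 533 without T8 of batch 1 or 2, 6 or 28 without T7 of batch 1 or 2, 2 without T11 of batch 1 and 6 or 0 without T10 of batch 1 or 2. Between T6 and T5 edgeR called 0 genes, with 1189 at an unadjusted p under 0.05, 50 by DESeq2, 1 with the authors' values and 193 in the fit to these plates alone. Root markers rose as a list (median 2.31, by batch 1.35 and 1.45, adjusted p = 0.0434), where 0 of 12 passed and 6 rose adjusted over the list alone. Whether T6 held more root tissue was not tested.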
